A study of Homo sapiens with 3 samples.

How the data were processed

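Total RNA was extracted with Trizol and libraries were made with a TruSeq RNA kit, per the labels' protocols, from cells labelled Hep3B. The design has 3 libraries, 1 each of control, USP39-KO and SIRT7-KO. The aligner, the counting program, the genome build and the annotation are not given in the sources used here. The authors deposited 1 table with a gene identifier, a gene length, read counts and FPKM for each library, per the file headers. The read counts are whole numbers per gene and were not normalized before the authors deposited them. The FPKM values deposited by the authors are the counts scaled by the listed length and by the library total. This was checked on every gene with reads (14711, 14361 and 14616 genes), each within a relative tolerance of 1e-06. FPKM carried no further information and was not used in the comparisons. No column of the table was left without a library.

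Gene symbols were taken by Ensembl identifier from GENCODE 29 and a table of gene names. Of 22827 identifiers, 19174 had a symbol of their own and 3178 were not in GENCODE 29. Identifiers without a symbol held 0.379%, 0.363% and 0.375% of counts in the control, USP39-KO and SIRT7-KO and stayed in all totals. No reads were listed for 7183 genes in any library. These include genes that nearly all cells use: 26 of 641 genes of 15 core lists had no read anywhere. Values of a few genes are not reported here. How the counting treated reads with several placements, overlapping genes or strand is not given in the sources used here, so values of genes with close copies or overlapping neighbours are uncertain. Whether polyadenylated RNA was selected is not given in the sources used here.

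Library totals were 19427940, 16630636 and 16151522 counts. Normalization used TMM factors from edgeR 4.0.16 (1.0000, 0.9896 and 1.0104) to give effective library sizes, from which CPM were computed. For each pair of libraries the log2 ratio was taken with a prior of 0.5 counts scaled to library size. Its 95% interval was the exact conditional binomial (Clopper-Pearson) interval of the 2 counts. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. A count of 0 allows up to 3 counts, or 0.154, 0.182 and 0.184 CPM. Folds against 0 reads, given as "at least", use that floor of 3 counts per library and leave out counting error of the other library. They lie above the lower bound of the exact interval, as for RADIL in USP39-KO against control (9.05-fold against 6.79-fold). Genes with at least 10 counts in 1 or more libraries were kept (12726). A gene was counted as higher or lower when the log2 ratio was at least 1 in size and the interval excluded 0. With 1 library per group no dispersion can be estimated, so edgeR and DESeq2 tests were not run. The chi-square statistic per degree of freedom over genes was 16.1 for USP39-KO against control, 30.4 for SIRT7-KO against control and 39.4 between the knockouts, so each pair differed by far more than counting error.

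The groups, the comparisons, the size rule, 37 gene lists, the rule for naming genes and the alternatives were fixed before the data were examined. For each knockout against control, the 12 protein-coding genes with the highest lower bound and the 12 with the lowest upper bound of the interval are named, and 5 each way for the direct comparison. For genes counted in both knockouts, up to 6 in each direction and 6 in opposite directions are named. For a described list, up to 4 members farthest from 0 with at least 100 counts in 1 of the 2 libraries and its most abundant member are named. Other list members that passed the size rule, such as CDH1, H4C3 and ACTA2, were named after their values were seen. USP39 and SIRT7 are always given. Of 1291 list members, 1261 were found in the table. A list median was set among 10000 random lists of the same size matched on mean log2 CPM in 20 bins, as a description of these libraries. A list stands apart below percentile 2.5 or above 97.5, and lists with under 5 measured members got no percentile. Random lists drew their genes independently. Percentiles may therefore overstate how far a list stands out when its members move together, as the mitochondrial-genome genes did.

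The overlap of the knockouts was compared with 100 simulated sets of 3 Poisson libraries drawn at the pooled rate of each gene. The plan had the real control held fixed. That version was run too and gave at most 0 genes higher and 1 lower in both, and a covariance of 3.72e-05, since it leaves out counting error of the control. Redrawing the control was chosen after the data were seen. Splitting of the control counts into 2 parts was repeated 20 times and the medians are given. Windows of neighbouring genes, GC content and length were read after the data were seen. GC content came from the longest GENCODE 29 transcript, and 99.0% of the genes with at least 300 summed counts had a value.

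The steps were tested on simulated counts for the 12726 genes, with 200 genes changed. For USP39-KO against control, 50 of 50 genes made 4-fold higher and 46 of 50 made 4-fold lower were recovered, and 46 of 12526 unchanged genes were called. For SIRT7-KO against control the numbers were 50 and 47 of 50, with 40 of 12526 unchanged genes called. For the direct comparison they were 49 and 46 of 50, with 43 called. Of 100 random lists of 30 genes, 5 stood apart. The simulated genes varied independently, so this share does not carry over to lists whose members vary together. A larger share of the fixed lists stood apart in each comparison of the real libraries. Alternatives changed the normalization (DESeq2 1.42.0 size factors, raw totals, TMM without mitochondrial and the 20 most abundant genes), the count filter, the size threshold, the error behind the interval, the prior and the matching of random lists. Computations used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.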

Results

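RNA was sequenced from cells labelled Hep3B, a human hepatocellular carcinoma line, in 3 libraries. One library came from control cells, one from cells with a knockout of USP39 (USP39-KO) and one from cells with a knockout of SIRT7 (SIRT7-KO). USP39 is a ubiquitin-specific protease homologue that acts in the spliceosome as part of the U4/U6.U5 tri-snRNP. SIRT7 is a nuclear NAD-dependent deacylase of the sirtuin family, known for its role at ribosomal DNA. The labels name the knockouts but not how they were made. The deposited table held 22827 genes, and counts summed to 19427940 in the control, 16630636 in USP39-KO and 16151522 in SIRT7-KO. Reads were found for 14711, 14361 and 14616 genes, in the same order. With 1 library per group there was no replicate check of any difference, so no test was made and no p-value is given. Each interval below is an exact 95% interval of the ratio of the 2 libraries' counts. It covers counting error only, and comparisons describe these libraries rather than the conditions.

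The targeted genes were read first. USP39 (ENSG00000168883; chromosome 2, 85602856 to 85649282, plus strand, in the GENCODE 29 annotation) had 1829 reads in the control, 1066 in USP39-KO and 1511 in SIRT7-KO. After normalization these were 94.1, 64.8 and 92.6 CPM (counts scaled to library size). USP39 was therefore at 0.688 times its control level in USP39-KO (log2 ratio -0.54, interval -0.65 to -0.43) and at 0.984 times in SIRT7-KO (log2 ratio -0.02, -0.12 to 0.08). SIRT7 (ENSG00000187531; chromosome 17, 81911939 to 81921323, minus strand) had 984, 808 and 608 reads, or 50.6, 49.1 and 37.3 CPM. SIRT7 was at 0.736 times its control level in SIRT7-KO (log2 ratio -0.44, -0.59 to -0.30) and at 0.969 times in USP39-KO (log2 ratio -0.04, -0.18 to 0.09). Each target was thus lowest in the library named for it, and neither passed the size rule of a 2-fold difference. Counts over a whole gene do not show an edited exon, a frameshift or the protein level.

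**Figure D1:**
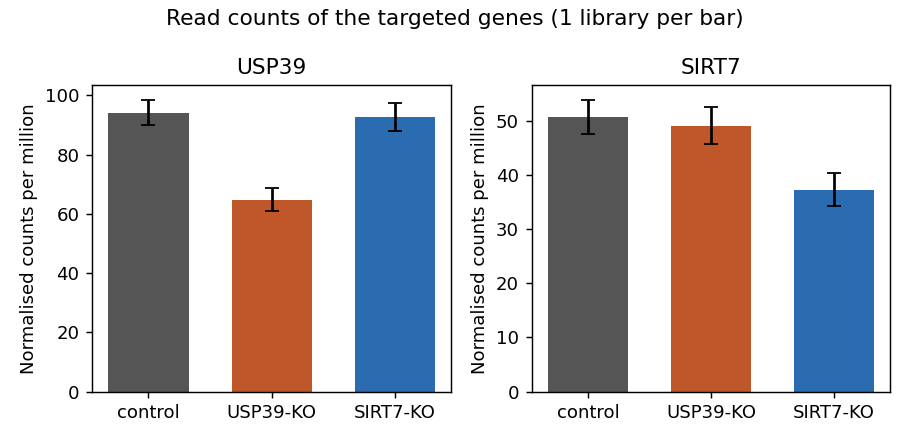
Normalised CPM of USP39 (left) and SIRT7 (right) in the control, USP39-KO and SIRT7-KO libraries, 1 library per bar, with exact 95% Poisson intervals of the count. USP39 lay at 64.8 in USP39-KO against 94.1 in the control, and SIRT7 at 37.3 in SIRT7-KO against 50.6.

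The labels name a liver cancer line, so genes of liver cells were read in each library as background. Albumin (ALB), alpha-fetoprotein (AFP), transthyretin (TTR), apolipoproteins APOB and APOA2 and glypican GPC3 were listed at 0 reads in all 3 libraries, where 0 reads allow up to 0.154, 0.182 and 0.184 CPM. Of 51 secreted hepatocyte proteins in the list fixed in advance, 22 had no read anywhere and 39 had under 10 reads in every library (76.5%, exact 95% interval 62.5 to 87.2%). Among 641 genes of 15 lists of widely used genes, such as those for ribosomes, spliceosomes and proteasomes, 32 did so (4.99%, 3.44 to 6.97%). Those 32 included RPL7A, RPS18 and SF3B4 at 0 reads, so a 0 in this table is not in itself evidence that a gene was silent. The urea cycle enzymes CPS1 and ASS1 were abundant, at 1369.5 and 2932 CPM in the control. The complement gene C3 had 299.8 CPM, the keratin KRT8 1939.6 CPM and the folate receptor FOLR1 1541 CPM in the control. The genes named here beyond the list rule were chosen after their values were seen.

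**Figure D2:**
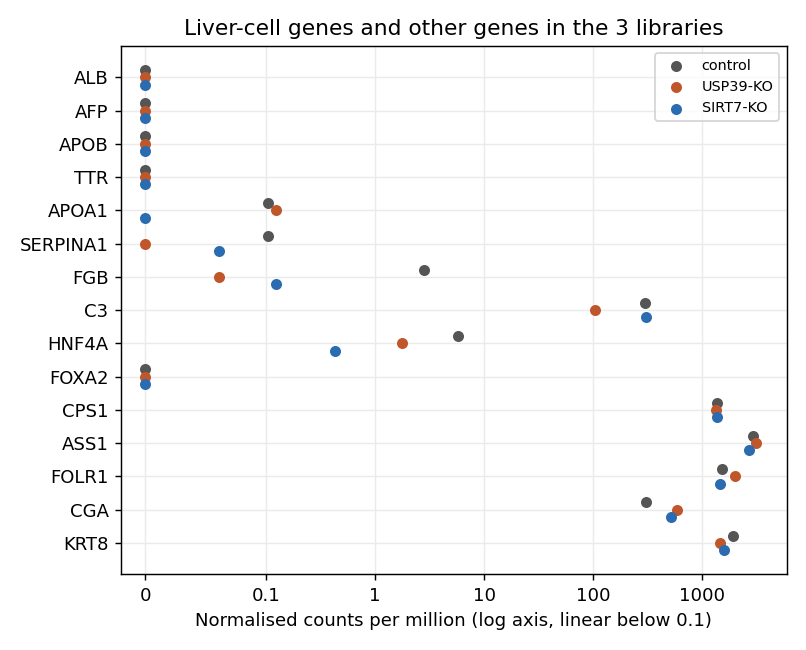
Normalised CPM of 15 genes in the control, USP39-KO and SIRT7-KO libraries (1 point each), on a log axis that is linear below 0.1. ALB, AFP, APOB, TTR and FOXA2 lie at 0 in all 3 libraries, while CPS1, ASS1, FOLR1 and KRT8 lie above 1000 CPM in every library.

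The first comparison, USP39-KO against control, asked which transcripts differed with USP39 knocked out. More genes were lower than higher in USP39-KO. List medians for cholesterol synthesis, the stress response and ER, lysosomes and the mitochondrial genome lay above nearly all matched random lists, although none of their 24, 34, 33 and 13 measured members passed the 2-fold rule. Medians of hypoxia and glycolysis genes, interferon-stimulated genes and histones lay below, with 2 of 33, 3 of 31 and 1 of 8 members lower by the rule and 1 interferon-stimulated gene higher. Transcript levels of splicing machinery genes differed little, although the list of other tri-snRNP and U4/U6 proteins stood apart (median 0.10, percentile 97.6). Counts over a whole gene do not show how transcripts were spliced, so these levels do not tell whether splicing changed.

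Of 12726 genes with at least 10 counts in 1 or more libraries, 189 were at least 2-fold higher in USP39-KO and 429 at least 2-fold lower, each with an interval excluding 0. Among genes with at least 200 reads in the 2 libraries together, 95.1% lay within 1.5-fold. PRUNE2 had the highest lower bound among the higher genes, with 28 reads in the control and 322 in USP39-KO (13.6-fold, 9.22 to 20.8). ABCC9, a subunit of ATP-sensitive potassium channels, was 7.34-fold higher (6.04 to 8.99), and TH, the rate-limiting enzyme of catecholamine synthesis, went from 2 reads to 58 (34.2-fold, 9.06 to 289). The transposase-derived gene PGBD5 was 7.48-fold higher, WSCD1 7.59-fold, FAM89A 7.62-fold and EPB41L3, a membrane skeleton protein, 6.53-fold. The transcription regulators PRDM16 (12.2-fold, 3.81 to 62.4, from 3 reads) and EN2 (4.60-fold) were also higher. RADIL, TAL2 and RTN1 had 23, 14 and 13 reads in USP39-KO and 0 in the control, or at least 9.05-fold, 5.51-fold and 5.12-fold higher against a floor of 3 counts per library.

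Among the lower genes, the homeobox gene BARX1 had 178 reads in the control and 4 in USP39-KO (37.7-fold lower, 14.5 to 140). PRKCH, a protein kinase C isoform, was 27.5-fold lower (15.9 to 52.1), and CHL1, a neural cell adhesion molecule, 16.3-fold lower (11.2 to 24.8). FGB, the fibrinogen beta chain, went from 55 reads to 1 (46.6-fold lower, 8.02 to 1873). The Ephrin receptor EPHB2 was 12.1-fold lower, the RNA-binding protein gene RBPMS 11.4-fold and EPS8L3 9.87-fold. PEG10, an imprinted retrotransposon-derived gene, was the most abundant of these, with 2212 reads against 261 (7.18-fold lower, 6.31 to 8.19). CPED1, the transporter SLCO2B1, the growth factor PTN and the embryonic globin HBE1 had 57, 29, 28 and 26 reads in the control and 0 in USP39-KO. They were lower by at least 16.1-fold, 8.19-fold, 7.91-fold and 7.34-fold.

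Cholesterol synthesis genes had a list median of 0.33 on the log2 scale in USP39-KO, with 21 of 24 measured members above 0. HMGCS1, the synthase of HMG-CoA, had a log2 ratio of 0.65 (0.58 to 0.73), the sterol carrier STARD4 0.62, DHCR7 0.42 and IDI1 0.41. None of the 24 passed the 2-fold rule. The median lay at percentile 100 among 10000 random lists of equal size matched on expression. The stress response and ER list had a median of 0.19 (percentile 100), with 29 of 34 members above 0 and none past the rule. The ER stress sensor ERN1 had 0.61, DNAJB9 0.57, ASNS 0.52 and the abundant amino acid transporter SLC7A5 0.26. Autophagy and lysosome genes had a median of 0.17 (percentile 99.99; 29 of 33 above 0), with NPC2 at 0.47 and TFEB at 0.42. All 13 protein-coding genes of the mitochondrial genome were above 0 (median 0.15, percentile 99.6), from 0.06 in MT-CO1 to 0.57 in MT-ATP8.

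Hypoxia and glycolysis genes had a median of -0.21 (percentile 0), with 27 of 33 members below 0. CA9, a hypoxia-induced carbonic anhydrase, was lower by the rule (log2 ratio -1.31, -1.81 to -0.84), as was EGLN3 (-1.25), and ADM, NDRG1 and PFKFB4 had -0.86, -0.76 and -0.68. Interferon-stimulated genes had a median of -0.24 (percentile 0.36), with ISG15 (-1.40), HERC5 (-1.18) and IFIH1 (-1.56) lower by the rule and HLA-C, from 2 reads to 10, higher (2.28, 0.33 to 5.79). Of 8 measured replication-dependent histones, 6 were below 0 (median -0.68, percentile 1.04), with H2AC6 at -0.73 and H1-2 at -0.62, and H4C3 was lower by the rule (13 reads to 1; log2 ratio -2.98, -8.87 to -0.73). Histone messages largely lack poly(A) tails, and their counts depend on the RNA selection. The epithelial list had a median of -0.21 (percentile 0.19), with KRT8 at -0.39 and CRB3 at -0.70, and none of 16 members past the rule. The mesenchymal and motility list had -0.12 (percentile 0.06), with TGFBI at -0.76 and LOXL2 at -0.59 but ZEB2 at 0.77. ACTA2, with 0 reads in the control and 5 in USP39-KO, was its 1 member past the rule (at least 1.97-fold higher). Hepatocyte enzymes and transporters had -0.47 over 12 measured members (percentile 1.00), of which 2 were lower by the rule and 0 higher. HPD was 1 of those lower (36 reads to 3, log2 ratio -3.16, -5.69 to -1.68), and the bilirubin conjugate exporter ABCC2 had -0.84. Secreted hepatocyte proteins did not stand apart (median -0.46, percentile 13.4), with 5 of 12 members above 0 and 2 lower by the rule, of which complement C3 went from 5825 to 1735 reads (log2 ratio -1.51, -1.59 to -1.43). Cytosolic ribosomal protein genes had a median of -0.05, with 49 of 67 below 0 (percentile 0.69).

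Splicing genes were read because USP39 belongs to the tri-snRNP. Their transcript levels do not measure splicing itself, which was not tested. The other tri-snRNP and U4/U6 proteins had a median of 0.10 (percentile 97.6; 18 of 22 above 0), with SART1 at 0.29, LSM7 at 0.28 and PRPF8 at 0.12. Other core spliceosome proteins had 0.04 (percentile 73.1), SR proteins and hnRNPs 0.05 (percentile 85.5) and the other ubiquitin-specific proteases 0.00 (percentile 37.6). No member of these 4 lists passed the 2-fold rule in USP39-KO. No cell cycle list stood apart in USP39-KO: S-phase genes had a median of -0.01 (percentile 21.1) and G2/M genes 0.04 (percentile 88.9). Apoptosis regulators (0.04, percentile 75.9), DNA repair genes (0.00, percentile 39.1) and proteasome subunits (-0.01, percentile 24.2) did not stand apart either.

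The counts rested on genes with few reads: with at least 100 counts in 1 or more libraries, 48 genes were higher and 126 lower in USP39-KO. The tri-snRNP list no longer stood apart under 4 of the 9 other settings, the hepatocyte enzyme list under both other count filters (medians -0.01 and -0.10), the epithelial list without a filter (-0.07), and the ribosomal protein and mitochondrial-genome lists against unmatched random lists.

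**Figure D3:**
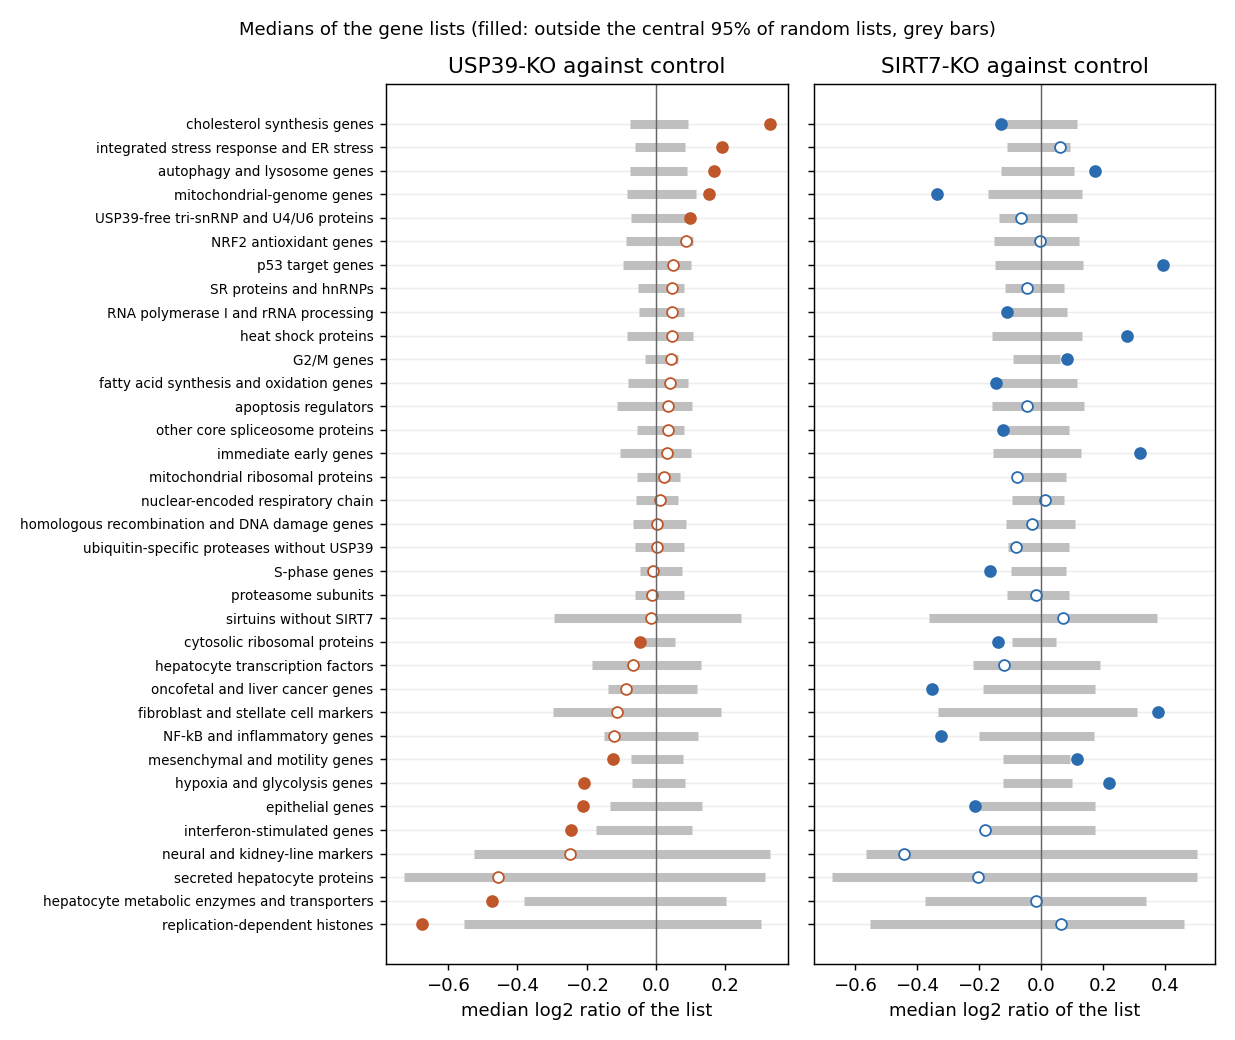
Median log2 ratio of each gene list in USP39-KO against control (left) and SIRT7-KO against control (right). Grey bars span the central 95% of medians of 10000 random lists matched on expression, and filled points lie outside it. Cholesterol synthesis had 0.33 in USP39-KO and -0.13 in SIRT7-KO, and hypoxia and glycolysis genes -0.21 and 0.22.

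The second comparison, SIRT7-KO against control, asked which transcripts differed with SIRT7 knocked out. The SIRT7-KO library lay farther from the control than USP39-KO did. FN1, the fibronectin gene, and SNAI1 were higher by the rule. List medians of p53 target genes and heat shock genes lay above nearly all matched random lists, with 3 of 27 and 0 of 15 members higher by the rule. Medians of the mitochondrial genome, NF-kB genes and ribosomal protein genes lay below, with 0 of 13, 3 of 18 and 0 of 67 members lower by the rule and 2 NF-kB genes higher.

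By the size rule 384 genes were higher and 515 lower in SIRT7-KO, and 89.9% of genes with at least 200 reads lay within 1.5-fold. TMEM212 had 367 reads in SIRT7-KO and 0 in the control, at least 145.6-fold higher. The protease inhibitor SPINK6 went from 18 to 1223 reads (80.9-fold; log2 ratio 6.30, 5.67 to 7.10) and EPB41L3 from 17 to 718 (50.3-fold, 31.2 to 86.8). FN1, encoding fibronectin, was the most abundant of the named higher genes, with 871 reads in the control and 4621 in SIRT7-KO (6.32-fold, 5.87 to 6.80). PRUNE2 was 10.5-fold higher, the metalloreductase STEAP4 11.2-fold, the transcription factor TCF4 8.14-fold, PJA1 9.15-fold and MGAT4A 8.28-fold. FGL1 went from 1 read to 48 (57.1-fold, 9.78 to 2304). ZNF711 and SHISA2 had 57 and 21 reads against 0, at least 22.6-fold and 8.33-fold higher.

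Among the lower genes, CHL1 went from 540 reads to 1 (454-fold lower, 81.1 to 17949), and BARX1 from 178 to 0, at least 49.8-fold lower. ADD3, a membrane skeleton protein, was 69.8-fold lower (35.2 to 162), and RYR1, the skeletal muscle calcium release channel, went from 251 reads to 3 (70.3-fold, 23.8 to 343). HKDC1, a hexokinase family member, went from 1036 reads to 29 (log2 ratio -4.89, -5.49 to -4.38), EPS8L3 from 396 to 9 and COL4A4, a basement membrane collagen, from 686 to 38 (15.2-fold). DRGX was 22.6-fold lower. SPINK5, a protease inhibitor, had the most reads of these, 4729 in the control against 350 (11.3-fold lower, 10.2 to 12.7). ANO3, ZFP37 and the mucin MUC5AC had 128, 55 and 41 reads in the control and 0 in SIRT7-KO, at least 35.8-fold, 15.4-fold and 11.5-fold lower.

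The mesenchymal and motility list had a median of 0.12 (percentile 99.0), with 24 of 36 members above 0. By the rule 4 members were higher and 1, TAGLN, was lower (-1.40). The higher members included FN1 (log2 ratio 2.66), the repressor of E-cadherin SNAI1 (1.23, 1.07 to 1.38) and ACTA2 (0 to 14 reads, at least 5.56-fold). The epithelial list had a median of -0.21 (percentile 1.58), with CRB3 (-2.67), CLDN1 (-1.72), EPCAM (-2.08) and CDH1 (24 to 8 reads, -1.29) lower by the rule. Fibroblast markers, a list for other cell types, had a median of 0.38 over 10 measured members (percentile 99.0), with COL6A1 at 0.39, FBLN1 at 0.35 and the abundant COL5A1 at 0.13. ACTA2 is in both the mesenchymal and the fibroblast list.

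The p53 target list had a median of 0.39 (percentile 100; 23 of 27 above 0). The death receptor gene FAS (1.38, 1.13 to 1.64), the cell cycle inhibitor CDKN1A (1.13, 1.03 to 1.23) and ZMAT3 (1.02) were higher by the rule, and SESN1 had 0.79. Of 26 immediate early genes, 7 were higher by the rule and none lower (median 0.32, percentile 100), among them FOSB (1.49), EGR1 (1.42), JUN (1.38) and FOS (1.23). MYC, the most abundant, had -0.24. All 15 measured heat shock genes were above 0 (median 0.28, percentile 99.98), with HSPA8 at 0.96, DNAJB1 at 0.78 and HSP90AA1 at 0.22. Hypoxia and glycolysis genes had a median of 0.22 (percentile 100; 26 of 33 above 0), with ANKRD37 (1.24) higher by the rule and the glucose transporter SLC2A3 (-1.93) lower. Autophagy and lysosome genes had 0.17 (percentile 99.9), with NPC2 (1.07) and MAP1LC3A (1.07) higher by the rule. G2/M genes had 0.08 (percentile 99.2) and S-phase genes -0.17 (percentile 0), with no member of either list past the rule.

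All 13 mitochondrial-genome genes were below 0 in SIRT7-KO (median -0.33, percentile 0), with MT-CO1 at -0.47 and MT-ND1 at -0.46. Mitochondrial-genome reads were 3.96% of all counts there, against 4.85% in the control and 5.29% in USP39-KO. Nuclear-encoded respiratory chain genes had a median of 0.01 (percentile 69.4). The stress response and ER list went both ways, with a median of 0.06 (percentile 91.2). Its members CHAC1 (-2.30), SLC7A11 (-1.88), ASNS (-1.68) and TRIB3 (-1.25), targets of the transcription factor ATF4, were lower by the rule, while the ER chaperone HSPA5 had 0.48. NF-kB genes had a median of -0.32 (percentile 0.08), with RELB (-2.16), BIRC3 (-1.35) and IL6 (-1.05) lower and SOCS3 (1.26) and CXCL3 (1.67) higher by the rule. Oncofetal and liver cancer genes had -0.35 (percentile 0.02), with the Wnt pathway regulators RNF43 (-2.84), AXIN2 (-1.05) and NKD1 (-1.46) among 6 lower by the rule. Fatty acid genes had -0.15 (percentile 1.64), with PPARGC1A at -1.11 and SCD at 0.35, and cholesterol synthesis genes -0.13 (percentile 2.39), with LSS at -0.77.

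SIRT7 is known to act at ribosomal DNA, and genes for ribosome production were read for that reason. Their transcript levels do not measure the output of ribosomal DNA itself. Cytosolic ribosomal protein genes had a median of -0.14 (percentile 0.02), with 55 of 67 below 0 and none past the rule. RPL26 had -0.67, RPS15A -0.54 and the abundant RPL4 -0.22. RNA polymerase I and rRNA processing genes had -0.11 (percentile 1.68), from -0.98 in UTP4 to 0.80 in TAF1A, with NPM1 at -0.09. Core spliceosome proteins had -0.12 (percentile 1.15), and mitochondrial ribosomal proteins -0.08 (percentile 5.53). The other sirtuins had 0.07 (percentile 65.7), with SIRT1 at 0.38.

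With at least 100 counts in 1 or more libraries, 136 genes were higher and 210 lower in SIRT7-KO, and the immediate early list (median 0.04), the oncofetal list (-0.02), the epithelial list (-0.15), the cholesterol list (-0.11) and the fibroblast list (0.24) no longer stood apart. The cholesterol list also lost its place under the 3 other normalizations, the epithelial list without a filter (-0.12), the G2/M list without genes of the shifted chromosome segments (0.03), the G2/M and fatty acid lists with the trend with GC content and length removed (0.05 and -0.10), and the core spliceosome, RNA polymerase I, G2/M, mesenchymal, cholesterol and fatty acid lists against unmatched random lists.

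The direct comparison of the knockouts does not involve the control. By the size rule 447 genes were higher and 640 lower in USP39-KO than in SIRT7-KO. RYR1 (73.0-fold, 24.7 to 357, from 3 reads), SIMC1 (62.0-fold, 16.8 to 517, from 2 reads), IGFN1 (27.9-fold, 14.9 to 58.7) and the fatty acid activating enzyme ACSL1 (19.8-fold, 14.6 to 27.4) were higher in USP39-KO, and ANO3 had 145 reads against 0, at least 47.9-fold. TMEM212 and SPOCK1 had 0 reads in USP39-KO against 367 and 84, at least 123-fold and 28.2-fold lower. SPINK6 was lower at a log2 ratio of -4.45, and PRKCH and the osteoprotegerin gene TNFRSF11B were 28.4-fold and 34.3-fold lower. Among the lists that stood apart were the mitochondrial genome (median 0.48, percentile 100, 13 of 13 above 0), cholesterol synthesis (0.44, percentile 100, 21 of 24 above 0) and hypoxia and glycolysis (-0.35, percentile 0, 28 of 33 below 0). By the rule, 1, 2 and 1 of their members were higher in USP39-KO and 0, 0 and 7 lower. In the stress response and ER list 7 members were higher in USP39-KO by the rule and none lower, among them CHAC1 (2.33), ASNS (2.19) and SLC7A11 (2.06), with a list median of 0.19 (percentile 99.8). Medians below the random lists were those of heat shock genes (-0.31, percentile 0.03), p53 targets (-0.27, percentile 0.05), mesenchymal genes (-0.26, percentile 0), histones (-0.72, percentile 1.88), fibroblast markers (-0.66, percentile 0.30) and immediate early genes (-0.24, percentile 0.27). Their members lower by the rule were 0 of 15, 2 of 27, 3 of 36, 2 of 8, 1 of 10 and 5 of 26. Medians above were those of core spliceosome genes (0.17, percentile 99.2) and S-phase genes (0.15, percentile 99.4), with no member past the rule, and of oncofetal genes (0.29, percentile 99.8), with 3 of 21 higher and 3 lower. Interferon-stimulated genes, with 4 of 31 higher and 2 lower by the rule, had a median of 0.20 (percentile 97.9), which turned to -0.22 with at least 100 counts in 1 or more libraries and no longer stood apart with the trend with GC content and length removed (0.16). The count filter left 221 genes higher and 281 lower, and the oncofetal list no longer stood apart under it (0.17). Autophagy and lysosome, epithelial and ribosomal protein lists stood apart on the same side in both knockouts against control. Between the knockouts their medians were -0.02, 0.02 and 0.08 (percentiles 28.8, 54.3 and 89.0), and none stood apart. By the rule 0, 4 and 0 of their members were higher in USP39-KO and none lower. A departure of the shared control library or a change common to both knockouts could give this.

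The comparisons with control share 1 control library, so their overlap was set beside simulated libraries. By the size rule 54 genes were higher and 161 lower in both knockouts than in the control. USP39-KO stood apart from both other libraries in more genes, 83 above and 174 below them, and SIRT7-KO in 224 and 240. Independent lists of these lengths would share 5.70 and 17.4 genes. In 100 simulated sets of 3 unchanged libraries the highest numbers were 9 and 6. With the real control held fixed and only the knockouts simulated, they were 0 and 1. PRUNE2, EPB41L3, TH, STEAP4, CLGN and FAM89A were higher in both. TH had 2, 58 and 23 reads in the control, USP39-KO and SIRT7-KO (13.7-fold higher in SIRT7-KO, 3.38 to 120), and CLGN, a testis chaperone, 0, 11 and 11, at least 4.33-fold and 4.37-fold higher. BARX1, CHL1, EPS8L3, FGB, PTN and the thyroid hormone receptor gene THRB were lower in both, THRB with 115 reads in the control and 9 in each knockout. In opposite directions, 16 genes were higher in USP39-KO and lower in SIRT7-KO (7.65 for independent lists) and 20 the reverse (12.9). ACSL1 was 2.70-fold higher in USP39-KO and 7.33-fold lower in SIRT7-KO, IGFN1 2.74-fold higher and 10.2-fold lower, and VEPH1 2.46-fold higher and 2.73-fold lower. TOX3 was 2.92-fold lower in USP39-KO and 2.92-fold higher in SIRT7-KO, the tyrosine catabolism enzyme HPD was 10.2-fold lower (3.21 to 51.6) and 3.47-fold higher, and SPOCK1 at least 3.11-fold lower and 9.09-fold higher.

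Across 11110 genes with at least 100 summed counts, the log2 ratios of the knockouts had Pearson's r 0.256 and Spearman's rho 0.114, where genes are not independent replicates. Their covariance was 0.0519, against a median of 0.00705 in the simulated sets. The difference of 0.0449 leaves out the shared counting error, but a departure of the single control library itself would enter it. Simulated r was 0.454. Random splitting of the control counts into 2 separate parts, 1 for each knockout, gave a covariance of 0.0446 and left 32 genes higher and 120 lower in both. Each part held fewer control reads than the whole, which by itself can change how many genes are counted.

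**Figure D4:**
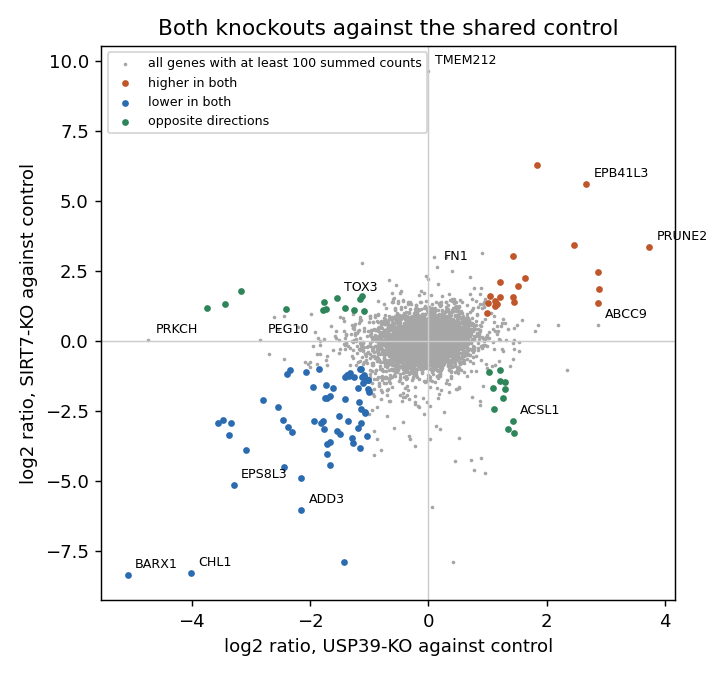
Log2 ratio of each gene in USP39-KO against control (horizontal) and in SIRT7-KO against control (vertical), for genes with at least 100 summed counts, with a small prior so that 0 counts can be drawn. Coloured points passed the 2-fold rule in both comparisons, and PRUNE2 and EPB41L3 lie at upper right, BARX1 and CHL1 at lower left.

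Neighbouring genes were also read together along the chromosomes, in 241 windows of 40 genes with at least 300 summed counts, placed by GENCODE 29 on GRCh38. In USP39-KO, 120 genes of chromosome 1 between 94.9 and 151.0 Mb had a median log2 ratio of -0.37, and 88.3% of them were below 0 (exact 95% interval 81.2 to 93.5%). All windows of chromosome 7 were above 0 in USP39-KO (medians 0.06 to 0.20), and those beyond the shuffles lay at its ends, with medians of 0.18 (0.193 to 38.9 Mb) and 0.20 (149.0 to 157.4 Mb). All windows of chromosomes 13 and 16 were above 0 there too (medians 0.001 to 0.129), none of them beyond the shuffles. In SIRT7-KO, separate stretches of the long arm of chromosome 1 had medians of 0.36 (151.0 to 172.4 Mb, 160 genes) and 0.30 (212.6 to 246.8 Mb, 120 genes), while windows between them had medians of -0.01 to 0.10. Genes of chromosome 14 between 100.4 and 105.3 Mb had a median of -0.48 (39 genes). RADIL, EN2 and EPS8L3 lie in the segments of USP39-KO, PGBD5 and FAM89A in those of SIRT7-KO, although both were also higher in USP39-KO, where that stretch was not shifted. Together, the segments of both comparisons held 746 of all 12726 kept genes. They held 14 of the 189 genes higher and 28 of the 429 lower in USP39-KO, and 30 of 384 and 23 of 515 in SIRT7-KO.

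**Figure D5:**
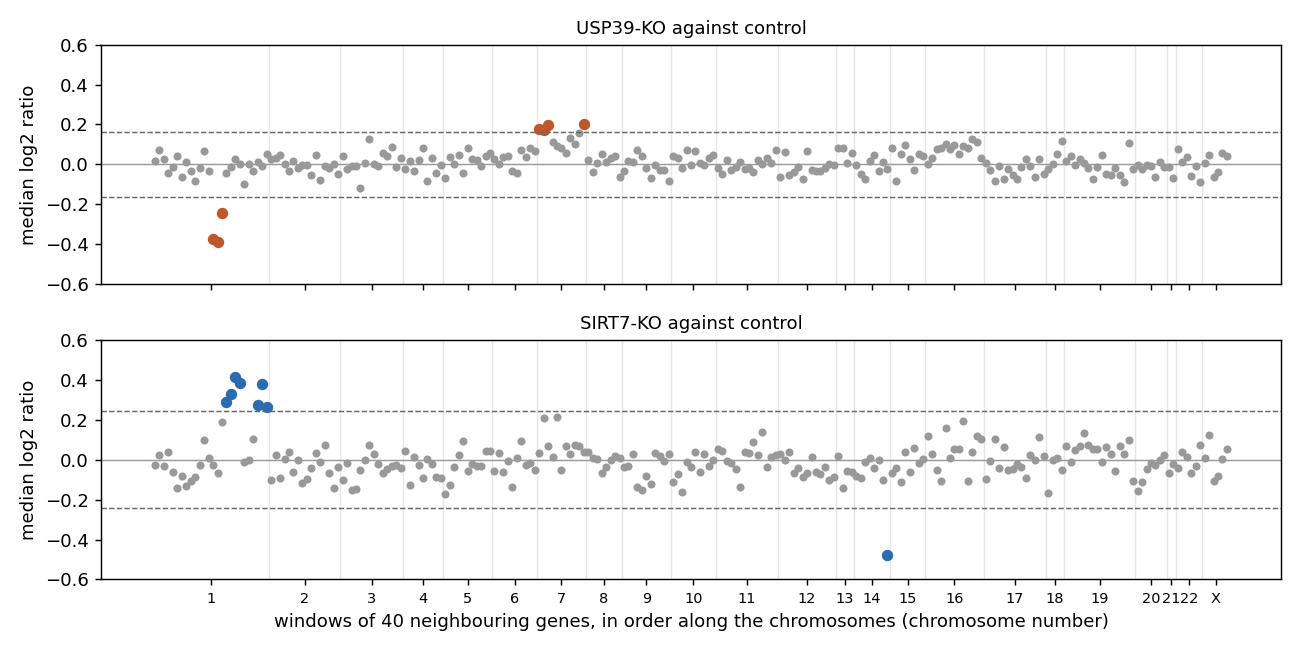
Median log2 ratio of windows of 40 neighbouring genes, in order along the chromosomes, for USP39-KO (top) and SIRT7-KO (bottom) against control. Dashed lines mark the largest window median among 100 shuffles of gene positions (0.161 and 0.243), and coloured windows lie beyond them, on chromosomes 1 and 7 in USP39-KO and on 1 and 14 in SIRT7-KO.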

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

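Of the alternatives, leaving out genes of shifted chromosome segments and removing the trend with GC content and length were chosen after the results were seen. No paired analysis was possible because each group had 1 library. With at least 100 counts in 1 or more libraries, genes higher and lower numbered 48 and 126 for USP39-KO against control, 136 and 210 for SIRT7-KO against control, 221 and 281 between the knockouts, and 11 and 47 in both knockouts; fewer genes were counted there by construction. A 1.5-fold threshold gave 406 and 814, 917 and 997, 1006 and 1316, and 112 and 286. An interval bound beyond 2-fold gave 49 and 141, 113 and 217, 188 and 237, and 11 and 54. Genes higher in both numbered 33 with an assumed replicate coefficient of variation of 0.2, and 32 with the control counts split. The correlation of the knockouts was 0.114 by Spearman and 0.140 with at least 1000 summed counts; the cause was not tested. The other 64 counts of genes stayed within 1.5 times. Under other normalizations and priors, all 316 log2 ratios of named genes stayed inside their main counting intervals. Those intervals have no bound on 1 side where a library had 0 reads, so this is a weak check for such genes. Of the list medians under alternatives, 895 kept their place, 29 no longer stood apart and 11 newly did. The 1 that reversed was that of interferon-stimulated genes between the knockouts, at -0.22 with at least 100 counts; the cause was not tested. Depth limits genes near 0 reads, where 3 counts amount to 0.154 to 0.184 CPM.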

Other observations

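All tests of explanations below, the marker genes of the HeLa line and the genes named in the opening paragraphs were chosen after the results were seen. Transcription factors of hepatocytes differed one by one, and their list did not stand apart in either knockout (medians -0.07, percentile 25.6, and -0.12, percentile 15.4). HNF4A, a regulator of liver genes, had 113 reads in the control, 29 in USP39-KO (log2 ratio -1.71, -2.36 to -1.12) and 7 in SIRT7-KO (-3.68, -5.11 to -2.67). Its relative HNF4G had 57, 123 and 5 reads, higher in USP39-KO (1.34) and lower in SIRT7-KO (-3.15). GATA6 had -0.98 in USP39-KO and was lower in SIRT7-KO (-1.18). ELOVL6, a fatty acid elongase, had 61, 9 and 2 reads, lower in USP39-KO (-2.46) and in SIRT7-KO (-4.40, -7.76 to -2.76).

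Markers of neurons and kidney lines had 6 measured members. INA, a neuronal intermediate filament, was lower in USP39-KO (739 to 162 reads, -1.95), while SNAP25 (-1.33) and PAX8 (-1.05) were lower and TUBB3 (1.13) higher in SIRT7-KO. Of 24 markers of blood and endothelial cells, 12 had no read in any library and 4 were measured. The ubiquitin protease USP2 was higher in SIRT7-KO (1.31, 1.07 to 1.57). Interferon-stimulated genes in SIRT7-KO had 6 members lower by the rule and none higher, among them HERC5 (-3.10), with a median of -0.18 (percentile 3.17).

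Most secreted hepatocyte genes were nearly absent from all 3 libraries, although C3 was not. Most hepatocyte enzymes and transporters were nearly absent too, although CPS1 and ASS1 were not. Reads dropped by the counting are argued against, since 76.5% of the secreted list had under 10 reads everywhere, against 4.99% of core genes (3.44 to 6.97%). The markers CGA, FOLR1, CDKN2A and KRT17, abundant in HeLa cells, had at least 112 CPM in every library. Cells of another line than the labels name, such as HeLa, may therefore account for the near absence. However, these 4 genes do not identify a line and the question stays open. STK11, read beside them but not weighed, had 12.3, 10.6 and 7.66 CPM in the control, USP39-KO and SIRT7-KO. A hepatic line with few liver transcripts was not tested.

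Runs of neighbouring genes were shifted together. A chance run is argued against, since the largest window median was 0.478 in size against 0.243 in shuffled positions for SIRT7-KO. GC content and gene length are argued against too, as each segment kept at least 0.954 of its shift once those trends were removed. With segments chosen on every other gene, 93.0% of the 57 genes left out lay on the same side in SIRT7-KO (83.0 to 98.1%) and 97.4% of 38 in USP39-KO, so a different number of copies between the cultures may account for these runs, as a hypothesis. That choice reached 3 and 2 windows and none of chromosome 7, and its origin, or another regional cause, cannot be read from 1 library per group.

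By the size rule 54 genes were higher and 161 lower in both knockouts, fewer than the 83 and 174 that set USP39-KO apart from both other libraries and the 224 and 240 for SIRT7-KO. Counting error of the shared control as the only source is argued against, since simulated sets gave at most 6 genes lower in both, against 161. Those sets held no changed genes, so they do not tell how many of the 161 that error added. A departure of the control library beyond counting error may account for the covariance of 0.0449 beyond the simulated one. A change common to both knockouts, or to knockout cultures as such, may equally do so, with a covariance of 0.0446 when the control counts were split. These cannot be told apart with 1 control library.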
